A study of Homo sapiens with 9 samples.

How the data were processed

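RNA of MOLT4 cells, grown in RPMI medium with 10% fetal bovine serum, was isolated with a miRvana kit, and ERCC spike-in RNA was added in proportion to cell number, per the labels' protocols. PolyA RNA was made into libraries with the SMARTer v4 low-input kit, per the labels' protocols, a kit that does not mark strand. HISAT, Cufflinks 2.0.0 and the genome build hg19 are named in the submitters' processing notes; the annotation, the counting settings and the normalization between libraries are not given in the sources used here. The deposited table holds the authors' FPKM values, with 1 column per library and 1 row per gene symbol. Its 23713 rows comprise 92 spike-in rows and 23621 gene rows, and no column was left unmapped. FPKM divides by transcript length and library size, and the values had been normalized further by the authors: spike-in rows were level across libraries (median log2 difference from DMSO of −0.03 in the libraries titled MI-389 and −0.01 in those titled sunitinib, over the 16 spike-in RNAs with a mean of at least 10 FPKM), and undetected rows stood near 0.1 FPKM in place of 0. A normalization to spike-in RNA added per cell lets a change in total messenger RNA appear as a shift of all genes. The most abundant spike-in RNA had a mean of 1523 FPKM, and 135 tested genes lay above it, beyond the range the spike-in RNAs cover.

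Libraries were assigned to groups by their titles, which the column names share. The source field crosses the compound names of all 6 treated libraries, and the alternative naming was carried through the analysis. No pair of libraries held identical values. Gene symbols were used as deposited; 12019 of the 12301 tested symbols matched a symbol or synonym in a RefSeq gene table of another build, from which only names and biotypes were used, so no coordinates are given. Mitochondrially encoded messenger RNAs were not analysed here. Rows of short non-coding RNAs (253 tested) were kept in the test but not named, since such rows can take reads of longer host genes; the MIR1244-2 and MIR1244-3 rows alone took 50.6% to 63.7% of the summed FPKM of a library.

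Genes with a mean of at least 1 FPKM over the 9 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with all 9 libraries and 3 groups in a single model, a variance trend, two-sided tests and Benjamini-Hochberg adjustment over 12301 genes. Fold changes in the text are ratios of mean FPKM, and log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes. Counts of genes changed at least 2-fold, and the setting of a fold change of at least 2, also used that scale. Of 33 gene lists fixed before the data were examined, 29 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over lists; an estimated correlation and fry were alternatives. The lists of mitochondrially encoded messenger RNAs and of B cell, myeloid, and epithelial and fibroblast markers had too few measured members. Medians of libraries were compared with exact permutation tests, in which 3 against 3 cannot give a p below 0.1. On simulated data built from the 12301 genes, 100 genes were changed by 1 on the log2 scale and 100 by 0.5. The model recovered 94 and 80 of these for the libraries titled MI-389 against DMSO. It recovered 94 and 69 for those titled sunitinib against DMSO, and 92 and 78 between the treated groups. Of the calls, 5.05%, 6.15% and 4.04% were false. The simulation drew each gene on its own, without shifts shared by a whole library, so these rates need not hold for the real libraries.

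Depth cannot be read from FPKM totals. In rows below 0.6 FPKM in every library that lay above the floor in exactly 2 libraries, the ratio of the heights above the floor gave relative depths, as the mode over 24 to 128 genes per pair of groups. Values near 0.1 FPKM rest on few reads or none.

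Named genes followed a rule fixed before the data were examined: for each comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 FPKM in the higher group and non-overlapping libraries, up to 4 called members with the smallest adjusted p of each list, and GSPT1, GSPT2, ETF1, CRBN, IKZF1, IKZF3, ATF4, DDIT3, ATF3, MYC and CDKN1A in every comparison. The text names a selection from this set, and some genes of it are not reported here. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, median centring, quantile normalization, rescaling to the 16 spike-in RNAs, the 6 compared libraries alone, a replicate block, no variance trend, robust variance, omission of short non-coding RNAs, a fold change of at least 2, compound names from the source field, and each library left out in turn. Cyclic loess between libraries, and omission of the genes above the most abundant spike-in RNA, were added after the data were seen. Abundance-matched lists were 10000 random draws within 50 abundance bins. Figures were drawn with matplotlib 3.10.9.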

Results

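RNA sequencing was carried out on MOLT4, an established human T-cell acute lymphoblastic leukemia (T-ALL) line, after 6 h with vehicle, with sunitinib or with MI-389. Sunitinib is a kinase inhibitor. MI-389 is described in the series design as a phthalimide conjugate; phthalimides bind cereblon, the substrate receptor of a ubiquitin ligase that conjugates of this kind recruit to other proteins. The series title names GSPT1, a translation termination factor, as an off-target of such conjugates. The comparisons below ask how the transcriptome of MOLT4 cells differed between each treated group and vehicle, and between the treated groups. There were 9 libraries in 3 groups of 3: vehicle (0.1% DMSO), libraries titled MI-389 and libraries titled sunitinib.

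The labels of the treated libraries conflict. The libraries titled MI-389 carry a source field that names sunitinib at 1 µM, and those titled sunitinib carry one that names MI-389 at 0.1 µM. The barcode list in the protocol and the column names of the deposited table follow the titles, so groups were taken from the titles and are written as titled throughout. No transcript in the design is known to check these labels. If the source field is right, every statement on one compound below belongs to the other. The doses stand in the crossed field, differ by a factor of 10 and were not matched, so differences between the treated groups are differences between compound and dose together.

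The deposited values were FPKM per gene symbol, and 12301 genes with a mean of at least 1 FPKM over the 9 libraries were tested. Total read counts were not used here because the table holds none. Low values moved in steps, and the size of a single step put both treated groups at a similar depth, about 1.37 times that of DMSO for the libraries titled MI-389 and 1.32 times for those titled sunitinib. These ratios are estimates from 87 and 94 genes near the floor. Across genes, every library correlated at r of 0.9946 or more with the others of its group on the log2 scale. The highest correlation of a library titled MI-389 with a library of another group was 0.975, while that of a library titled sunitinib was 0.994. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

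In the libraries titled MI-389, 31 of 35 genes of the ATF4 list and 16 of 18 immediate early genes were higher than in DMSO after 6 h, a few of them from low levels, while 19 of 20 heat shock response genes were lower. With an estimated correlation these lists had an adjusted p = 0.55, 0.55 and 0.78. Fry, which tests a list without the other genes, gave them adjusted p = 1.14e-06, 2.06e-07 and 6.97e-05. JUN, a subunit of the AP-1 transcription factor, stood at 794 ± 23.1 FPKM (SD, n = 3) against 6.59 ± 0.864 in DMSO, a 121-fold difference. CHAC1, a glutathione-degrading enzyme induced by ATF4, stood at 150 ± 7.30 against 1.81 ± 0.879 FPKM. EGR1, a zinc finger transcription factor, stood at 121 ± 5.40 against 1.62 ± 0.459 FPKM. HSPA5, the main chaperone of the endoplasmic reticulum, fell 4.67-fold, from 446 ± 34.3 to 95.6 ± 3.98 FPKM, and HSPA8, a constitutive cytosolic chaperone, fell 3.91-fold, from 4162 ± 519 to 1063 ± 36.4 FPKM.

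**Figure D1:**
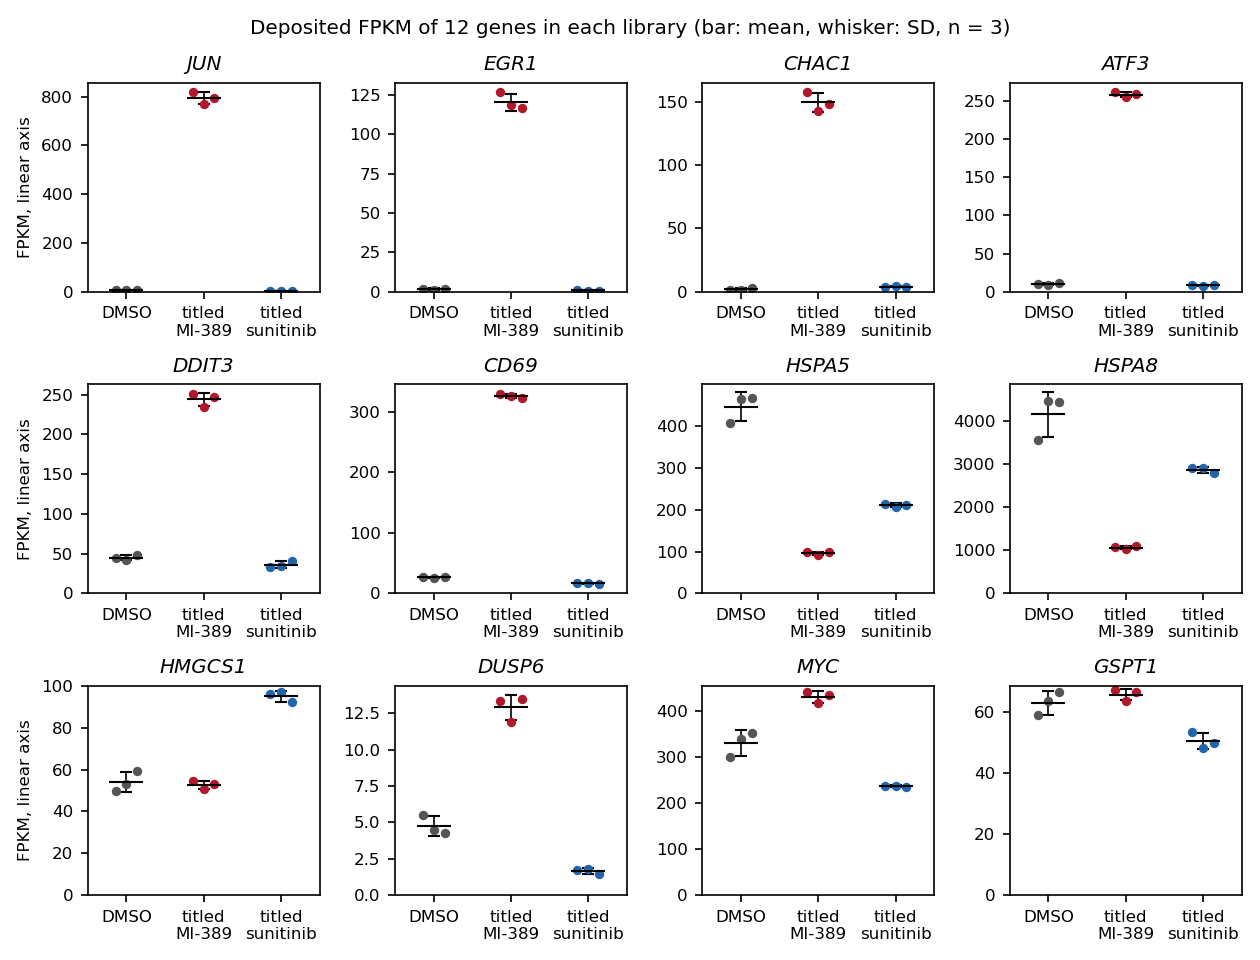
Deposited FPKM (linear axes from 0) of 12 genes in each library of DMSO and of the groups titled MI-389 and sunitinib; points are libraries, horizontal bars are means and whiskers are SDs (n = 3). JUN reached a mean of 794 FPKM in the libraries titled MI-389 against 6.59 in DMSO and 3.36 in those titled sunitinib, whereas HSPA5 was below DMSO in both treated groups.

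By limma with Benjamini-Hochberg adjustment, 6979 of the 12301 genes passed an adjusted p of 0.05 between the libraries titled MI-389 and DMSO, 3502 higher and 3477 lower. At least 2-fold changes were seen for 294 of the higher and 129 of the lower genes. The 3 libraries of each group did not overlap for 60.2% of genes, where chance gives 10%. The median log2 difference over all genes was 0.00 (−0.002). The medians of single libraries averaged 4.74 ± 0.056 on the log2 scale against 4.66 ± 0.089 in DMSO (SD, n = 3; exact permutation p = 0.3, two-sided, smallest possible 0.1). The share of higher calls was 50.2% as deposited and 39.4% (3222 higher, 4956 lower) with each library centred on its median.

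Of 35 measured genes of the ATF4 pathway and integrated stress response, 31 rose and 1 fell, with a median log2 difference of 1.63 (camera, adjusted p = 2.07e-16; adjusted p = 0.55 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 9.96 ± 1.41 to 258 ± 3.30 FPKM. DDIT3, which encodes the pro-apoptotic factor CHOP, rose 5.46-fold to 244 ± 8.10 FPKM, and ATF4 itself rose 1.79-fold to 1202 ± 22.3 FPKM. SLC7A11, the cystine transporter, rose 16.6-fold, PCK2, a mitochondrial carboxykinase, rose 15.6-fold and SESN2, a stress-induced regulator of mTOR signalling, rose 13.6-fold. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 13 rose and 2 fell (adjusted p = 0.000446; adjusted p = 0.78 with an estimated correlation). CARS rose 4.76-fold, GARS 2.94-fold, MARS 2.35-fold and TARS 2.26-fold.

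Immediate early genes, which are transcribed within minutes of a stimulus, moved in the same direction. Of 18 measured, 16 rose and 1 fell, with a median log2 difference of 1.40 (adjusted p = 7.87e-10; adjusted p = 0.55 with an estimated correlation). Besides JUN and EGR1, CD69, an early activation marker of lymphocytes, rose from 26.3 ± 0.996 to 326 ± 3.86 FPKM, and FOS reached 23.4 ± 0.809 FPKM from 0.483 ± 0.0983. GADD45G, a stress-inducible growth regulator, reached 18.8 ± 2.04 FPKM from 0.145 ± 0.0603, a value close to the floor of the table. The ERK feedback list holds genes that dampen ERK signalling and others downstream of it. Of its 8 measured genes, 6 rose and none fell (adjusted p = 0.0203, and 0.78 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.0611) and cyclic loess (0.0688). DUSP6, an ERK phosphatase, rose 2.72-fold and SPRY2, a receptor tyrosine kinase antagonist, 1.86-fold.

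Of 20 heat shock response genes, 19 fell and none rose, with a median log2 difference of −0.90 (adjusted p = 7.87e-10; adjusted p = 0.78 with an estimated correlation). HSPA1A fell 3.94-fold and HSPA1B 3.86-fold; these neighbouring genes are nearly identical, so the division of reads between them is uncertain. The unfolded protein response list of the endoplasmic reticulum split. Of 20 genes, 15 fell and 3 rose (median −0.56, adjusted p = 0.000277; adjusted p = 0.78 with an estimated correlation). HSPA5 and MANF, a secreted survival factor of the endoplasmic reticulum that fell 3.11-fold, were among the falls, while EDEM1 and HERPUD1, which act in degradation of misfolded proteins, rose 2.31-fold and 2.07-fold.

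Of 30 targets and factors of nonsense-mediated decay, the pathway that degrades transcripts with early stop codons, 18 rose and 3 fell (median 0.27, and 0.42 after cyclic loess; adjusted p = 0.00522; adjusted p = 0.82 with an estimated correlation). EPB41L4A-AS1 rose 2.38-fold, GAS5 rose from 516 ± 32.5 to 946 ± 20.8 FPKM and ZFAS1 from 501 ± 49.4 to 900.5 ± 33.9 FPKM; these non-coding genes host small nucleolar RNAs. CLK1, a kinase of splicing factors, rose 1.60-fold. EPB41L4A-AS1 and ZFAS1 lie antisense to other genes. The library kit does not mark strand, so reads of overlapping genes may enter their rows.

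Of 27 genes of G2/M and mitosis, 23 fell and none rose (median −0.41, adjusted p = 3.94e-07), and of 24 of G1/S and DNA replication, 18 fell and 2 rose (median −0.42, adjusted p = 1.83e-05). PCNA, the replication clamp, fell from 1723 ± 168 to 711 ± 28.7 FPKM, CCNE1 2.63-fold and CCNE2 2.35-fold; these are the E-type cyclins. KIF20A, a mitotic kinesin, fell 1.92-fold, PLK1, a mitotic kinase, 1.93-fold and CCNB1, a mitotic cyclin, 1.49-fold. Of 23 hypoxia and glycolysis genes, 21 fell and 2 rose (median −0.64, adjusted p = 1.02e-05). LDHA, lactate dehydrogenase, fell 1.81-fold, while the rises were SLC2A3, a glucose transporter, 3.01-fold and VEGFA, an angiogenic factor, 5.98-fold. NRF2 targets, which defend against oxidants, fell in 10 of 13 cases and rose in none (median −0.29, adjusted p = 0.00164), with PRDX1, a peroxiredoxin, 1.71-fold lower. Each of these 4 lists had an adjusted p = 0.78 with an estimated correlation. After cyclic loess the G2/M median was −0.26 and the G1/S median −0.23.

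Of 78 cytosolic ribosomal protein genes, 57 fell and none rose (median −0.28, adjusted p = 8.35e-09; adjusted p = 0.78 with an estimated correlation), but the median turned to 0.02 after quantile normalization, where the list did not pass (0.532), and to 0.13 after cyclic loess, where camera placed it above the other genes (1.44e-05). The list's median log2 value was 11.81, 12.13 and 12.10 in DMSO replicates 1 to 3. It was 11.73, 11.69 and 11.77 in the libraries titled MI-389, so DMSO replicate 1 lay closer to these than to the other controls. RPL23 was 1.49-fold and RPL38 1.41-fold lower. The call of RPL38 was lost without a filter on low values (adjusted p = 0.0562). Nuclear-encoded oxidative phosphorylation genes fell in 21 of 27 cases and rose in none (median −0.29, adjusted p = 8.97e-05; adjusted p = 0.78 with an estimated correlation); after quantile normalization that median was −0.08 and after cyclic loess 0.01, and the call was lost there (0.686) and after quantile normalization (0.17). Proteasome subunits fell in 16 of 31 cases and rose in 3 (median −0.18, adjusted p = 0.0130; adjusted p = 0.84 with an estimated correlation), with PSMB2 1.88-fold lower; their median was 0.02 after quantile normalization and 0.08 after cyclic loess, and the call was lost in both (0.532 and 0.192).

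Adjusted over the list alone, the counts were 14 higher and 2 lower for synthetases, 3 and 16 for the unfolded protein response, 18 and 5 for nonsense-mediated decay, 2 and 19 for G1/S and DNA replication and 0 and 65 for ribosomal proteins. Those of the other lists named above were as given. Of the largest falls outside the lists, EFNA3, an ephrin, fell 5.71-fold, CDK2AP2, a CDK2-associated protein, 3.17-fold and RAB3A, a GTPase of vesicle release, by 1.75 on the log2 scale.

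The libraries hold transcripts only, so in no comparison do their values show whether GSPT1 or another protein was degraded. GSPT1 stood at 65.8 ± 1.91 against 63.2 ± 3.95 FPKM in DMSO and did not pass the test, with a log2 difference of 0.06 (95% interval −0.08 to 0.20, adjusted p = 0.43 by limma). It passed after cyclic loess, at 0.09 (adjusted p = 0.0318), and turned to −0.02 with median centring. GSPT2, a paralog of GSPT1, lay at the floor of the table in every group (0.132, 0.108 and 0.101 FPKM in DMSO and the groups titled MI-389 and sunitinib) and was not tested. ETF1, the partner of GSPT1 in termination, rose 1.18-fold to 174 ± 2.62 FPKM. CRBN, which encodes cereblon, rose 1.41-fold to 53.6 ± 3.73 FPKM. IKZF3, a lymphoid transcription factor degraded through cereblon by related drugs, rose 1.64-fold, while IKZF1, its relative, stood at 92.2 ± 1.81 against 95.1 ± 7.85 FPKM without passing the test; that IKZF1 difference of −0.04 turned to 0.03 after quantile normalization, 0.05 after cyclic loess and 0.01 without DMSO replicate 3, and passed at −0.12 with median centring (adjusted p = 0.0206). Of the 11 measured genes of this list 5 rose, CSNK1A1 (1.72-fold) among them, and 3 fell, RBX1 (1.75-fold) among them, both counts also when adjusted over the list alone (camera, adjusted p = 0.52). MYC rose 1.30-fold to 431 ± 13.2 FPKM, and CDKN1A, a p53-induced cell cycle inhibitor, stood at 1.57 ± 0.202 against 1.32 ± 0.105 FPKM without passing the test.

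In the libraries titled sunitinib, 13 of 24 genes of cholesterol synthesis and uptake were higher than in DMSO, while 24 of 24 of G1/S and DNA replication, 21 of 30 of MYC and ribosome biogenesis, 8 of 8 of ERK feedback and 16 of 20 each of the unfolded protein and heat shock responses were lower. These lists had an adjusted p = 0.56 or 0.66 with an estimated correlation, and 0.00135 to 0.0134 by fry. HMGCS1, an early enzyme of cholesterol synthesis, rose 1.76-fold, from 54.1 ± 4.94 to 95.1 ± 2.57 FPKM, and LSS, lanosterol synthase, rose 1.62-fold to 89.2 ± 4.19 FPKM. HSPA5 fell 2.12-fold to 211 ± 3.88 FPKM. DUSP6 fell 2.87-fold, from 4.75 ± 0.682 to 1.65 ± 0.197 FPKM, and MYC 1.40-fold to 236 ± 1.86 FPKM.

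Of 12301 genes, 2370 passed the adjusted p of 0.05, 291 higher and 2079 lower. Changes of at least 2-fold on the log2(FPKM + 1) scale were seen for 4 of the higher and 14 of the lower. The groups did not overlap for 35.2% of genes, where chance gives 10%. The excess of lower genes went with a median log2 difference over all genes of −0.10. The medians of single libraries averaged 4.58 ± 0.025 against 4.66 ± 0.089 in DMSO (SD, n = 3; exact permutation p = 0.2, two-sided, smallest possible 0.1). The higher share was 12.3% as deposited and 11.96% after rescaling to spike-in RNA, but 40.5% (1270 higher, 1866 lower) with median centring, 46.1% (1696 and 1981) after quantile normalization and 48.6% (1852 and 1962) after cyclic loess. The count moved more than 1.5-fold when single libraries were left out: it was 4244 without DMSO replicate 1, 1572 without DMSO replicate 2, and 1529, 929 and 995 without replicates 1, 2 and 3 of the group titled sunitinib.

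Of 24 genes of cholesterol synthesis and uptake, 13 rose and none fell (median 0.27, adjusted p = 8.14e-18; adjusted p = 0.56 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, rose 1.30-fold and TM7SF2, a sterol reductase, 1.49-fold. All 24 measured genes of G1/S and DNA replication fell (median −0.52, adjusted p = 2.05e-14; adjusted p = 0.56 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 250.003 ± 14.8 to 145 ± 5.17 FPKM, CDC6, a licensing factor, 1.58-fold, MCM10, a replication initiation factor, 1.62-fold and CCNE2 1.69-fold. Of 27 genes of G2/M and mitosis, 3 fell and none rose (median −0.06, adjusted p = 0.685); this median was above 0 with median centring (0.03), quantile normalization (0.07) and cyclic loess (0.07), and camera placed the list above the other genes after quantile normalization (0.00618) and cyclic loess (0.00777).

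Of 30 genes of the MYC and ribosome biogenesis list, 21 fell and none rose (median −0.37, adjusted p = 2.30e-09; adjusted p = 0.66 with an estimated correlation), among them RRS1 (1.41-fold), WDR43 (1.34-fold) and DKC1 (1.30-fold), which act in making ribosomes. All 8 ERK feedback genes fell (median −0.47, adjusted p = 4.50e-05; adjusted p = 0.56 with an estimated correlation); SPRY2 fell 1.61-fold and ETV5, an ETS factor downstream of ERK, fell to 0.643 ± 0.0233 from 1.85 ± 0.448 FPKM. Of 20 unfolded protein response genes 16 fell and none rose (median −0.46, adjusted p = 2.62e-09; adjusted p = 0.56 with an estimated correlation). HSP90B1, an endoplasmic reticulum chaperone, fell 1.79-fold, MANF 1.87-fold, SDF2L1 1.83-fold and XBP1, a transcription factor of the response, 1.70-fold. Heat shock response genes fell in 16 of 20 cases and rose in none (median −0.36, adjusted p = 2.35e-07; adjusted p = 0.66 with an estimated correlation), HSPA1A and HSPA1B 1.56-fold each. After quantile normalization and cyclic loess the medians were −0.23 and −0.23 for MYC and ribosome biogenesis and −0.23 and −0.24 for heat shock.

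The ATF4 list moved both ways, with 10 rises and 5 falls among 35 (median 0.12, adjusted p = 3.95e-07; adjusted p = 0.66 with an estimated correlation). Its median was 0.20 with median centring, 0.22 after quantile normalization and 0.23 after cyclic loess. Fry, which tests a list without the other genes, gave it an adjusted p = 0.18. PCK2 rose 1.79-fold and SLC7A11 1.56-fold, and CHAC1 stood at 4.02 ± 0.179 FPKM, 2.22-fold above DMSO. ATF4 stood at 759 ± 17.3 against 671 ± 79.3 FPKM without passing the test (adjusted p = 0.14), but passed with median centring (adjusted p = 0.0109), quantile normalization and cyclic loess. DDIT3 was lower, at 36.3 ± 4.08 against 44.7 ± 3.37 FPKM (adjusted p = 0.0347), a call lost without a filter on low values (0.094), with only the 6 libraries compared (0.0892), with median centring (0.0705), quantile normalization (0.0933) and cyclic loess (0.143), and when DMSO replicate 3 (0.101), replicate 1 or 3 of the group titled MI-389 (0.0539 and 0.0597), or replicate 1 or 2 of that titled sunitinib (0.11 and 0.122) was left out. ATF3, at 8.41 ± 0.348 FPKM, did not pass the test but passed without DMSO replicate 2 (adjusted p = 0.0193) and with robust variance (0.0393). Of 18 immediate early genes 9 fell and 1 rose (adjusted p = 0.0605, and 0.019, 0.0034 and 0.00777 with median centring, quantile normalization and cyclic loess), JUN falling 1.96-fold to 3.36 ± 0.534 FPKM and CD69 1.58-fold. EGR1, named here after its values were seen, was called lower at 0.753 ± 0.125 FPKM (adjusted p = 0.0134), a call lost without replicate 2 (0.055) or 3 (0.0522) of the group titled sunitinib, without a filter on low values (0.0565) and with only the 6 libraries compared (0.0605).

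**Figure D2:**
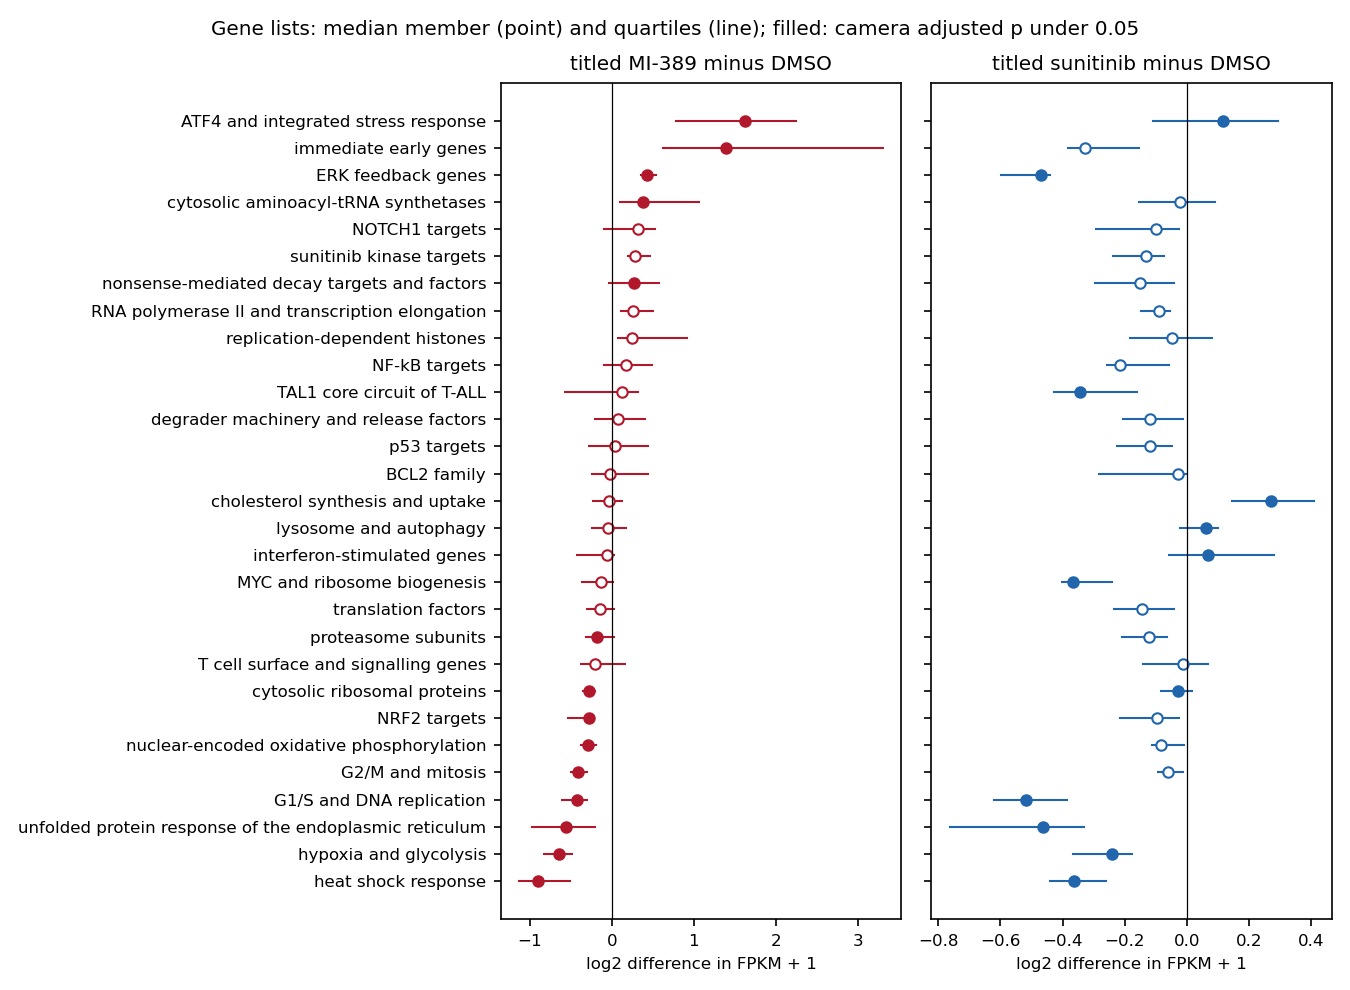
Log2 difference in FPKM + 1 from DMSO for the members of 29 gene lists in the libraries titled MI-389 (left) and titled sunitinib (right), on separate axes; points are list medians, lines run from the lower to the upper quartile of members, and filled points mark a camera adjusted p under 0.05. The ATF4 list had a median of 1.63 on the left and 0.12 on the right, and the cholesterol list −0.03 and 0.27; the ribosomal protein median on the left turned to 0.13 after cyclic loess.

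Smaller list differences also passed in this comparison. Interferon-stimulated genes rose in 4 of 18 cases and fell in none (median 0.07, adjusted p = 6.47e-05; adjusted p = 0.56 with an estimated correlation), IFIT2 1.42-fold and ISG20, a nuclease, 1.69-fold. Of 23 hypoxia and glycolysis genes 9 fell and none rose (median −0.24, adjusted p = 0.0207; adjusted p = 0.86 with an estimated correlation). Lysosome and autophagy genes, with 1 rise and 2 falls among 29, were placed above the other genes by camera (median 0.06, adjusted p = 0.000196; adjusted p = 0.66 with an estimated correlation). None of the 78 ribosomal protein genes was called; camera placed the list above the other genes (adjusted p = 0.0163; adjusted p = 0.94 with an estimated correlation) although its median was −0.03, and that median turned to 0.06 with median centring. Camera sets each list against the other genes, and the median over all genes was −0.10. Fry, which tests a list without the other genes, gave adjusted p = 0.11 for interferon, 0.53 for lysosome and 0.87 for ribosomal proteins. For hypoxia fry gave 0.032. With median centring, quantile normalization and cyclic loess the medians were 0.16, 0.13 and 0.13 for interferon-stimulated genes and −0.16 in each for hypoxia. Those for lysosome were 0.15, 0.14 and 0.14. Adjusted over the list alone, the counts of higher and lower genes were 17 and 1 for cholesterol, 0 and 29 for MYC and ribosome biogenesis, 1 and 17 for the unfolded protein response, 0 and 17 for heat shock, 12 and 5 for ATF4, 2 and 12 for immediate early genes, 6 and 2 for interferon, 1 and 13 for hypoxia, 1 and 1 for lysosome and 0 and 2 for G2/M, and as given for the other lists of this comparison named above.

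Among the largest single changes, ASS1, an enzyme of arginine synthesis, rose 1.97-fold, BTG2, an antiproliferative gene, 1.89-fold, DICER1-AS1, an antisense transcript, 1.80-fold and MT1F, a metallothionein with close paralogs, 1.74-fold; the call of DICER1-AS1 was lost without DMSO replicate 2 (adjusted p = 0.0696) or 3 (0.0629) and without replicate 1, 2 or 3 of the group titled sunitinib (0.0509, 0.0813 and 0.0735), and that of MT1F without DMSO replicate 2 (0.0685) or 3 (0.0767) and without replicate 1 or 3 of that group (0.0695 and 0.0998). Without a filter on low values the calls of DICER1-AS1 (0.0892) and MT1F (0.1) were also lost, as was that of MT1F with only the 6 libraries compared (0.0599). Since the library kit does not mark strand, reads of an overlapping gene may also enter the DICER1-AS1 row. TNFRSF8, a tumor necrosis factor receptor, fell 2.60-fold, SIX6, a homeobox factor, 1.89-fold and IGLL3P, a transcribed pseudogene that may share reads with related genes, 2.16-fold. PRR4 fell 2.22-fold, a call lost without replicate 2 of the group titled sunitinib (0.0708) and without a filter on low values (0.0754). BGLAP stood at 0.211 ± 0.0201 FPKM against 6.45 ± 4.21 in DMSO, where the libraries ranged from 1.93 to 10.3 FPKM; its call was lost without a filter on low values (adjusted p = 0.0505). GSPT1 fell from 63.2 ± 3.95 to 50.7 ± 2.66 FPKM (log2 difference −0.31, 95% interval −0.45 to −0.18, adjusted p = 0.00969), and IKZF1 fell 1.25-fold; of 11 measured genes of the degrader machinery 3 fell and none rose, and 5 fell adjusted over the list alone (camera, adjusted p = 0.46). CRBN (38.0 ± 0.353 FPKM), IKZF3 (6.59 ± 0.392), ETF1 (126 ± 4.77) and CDKN1A (1.04 ± 0.203) did not pass the test; the differences of CRBN (−0.01) and IKZF3 (−0.05) turned positive with median centring, quantile normalization and cyclic loess, that of CRBN also without DMSO replicate 3 (0.02) and without replicate 1 of the group titled sunitinib (0.0012). ETF1 was called lower after quantile normalization (adjusted p = 0.0447), cyclic loess (0.0419) and rescaling to spike-in RNA (0.0448), with robust variance (0.0254), without short non-coding RNAs (0.0279) and without DMSO replicate 1 (0.000825).

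The direct comparison of the treated groups placed 31 of 35 genes of the ATF4 list and 17 of 18 immediate early genes higher in the libraries titled MI-389 (adjusted p = 0.62 for each list with an estimated correlation). Fry gave these lists adjusted p = 1.62e-06 and 1.13e-07. JUN was 237-fold and CD69 19.6-fold higher in the libraries titled MI-389 than in those titled sunitinib, ATF3 30.7-fold, CHAC1 37.3-fold and DDIT3 6.73-fold. ARRDC4, an arrestin-domain gene, stood at 80.9 ± 5.94 against 5.57 ± 0.507 FPKM. The 8 largest falls by the naming rule were MXD3, a MYC-network repressor (3.17-fold), SNN (2.96-fold), HSPA8 (2.70-fold), SOX12 (3.32-fold), EFNA3 (3.71-fold), RAB3A (3.53-fold), MUSTN1 (2.91-fold) and H3F3AP4 (2.53-fold); H3F3AP4 is a histone pseudogene whose reads may come from its parent gene.

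Of 12301 genes, 6927 passed, 4427 higher and 2500 lower in the libraries titled MI-389, and the groups did not overlap for 69.4% of genes, where chance gives 10%. At least 2-fold changes were seen for 362 higher and 55 lower genes. The median log2 difference was 0.08, and the medians of single libraries averaged 4.74 ± 0.056 and 4.58 ± 0.025 (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest possible). The higher share was 63.9% as deposited, 40.3% (3279 higher, 4863 lower) with median centring, 46.1% (3791 and 4426) after quantile normalization and 50.2% (4075 and 4040) after cyclic loess; median centring moved the median from 0.08 to −0.08.

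Of 35 genes of the ATF4 list 31 were higher and 1 lower in the libraries titled MI-389 (median 1.48, adjusted p = 9.71e-13), as were 17 and 1 of 18 immediate early genes (median 1.49, adjusted p = 2.21e-09) and all 8 ERK feedback genes (median 0.90, adjusted p = 0.000668), with DUSP6 7.81-fold higher and SPRY2 higher by 1.31 on the log2 scale. Of 24 cholesterol genes 18 were lower and 1 higher (median −0.33, adjusted p = 4.64e-07), LSS 2.19-fold, HMGCS1 1.81-fold and SQLE 1.86-fold. Heat shock genes were lower in 17 of 20 cases and higher in none (adjusted p = 4.16e-08), G2/M genes in 20 of 27 and higher in none (adjusted p = 1.69e-08), and hypoxia and glycolysis genes in 17 of 23 and higher in 2 (adjusted p = 3.35e-05). KIF20A was 1.84-fold and PLK1 1.90-fold lower. Interferon-stimulated genes were lower in 11 of 18 cases and higher in 2 (adjusted p = 0.00302), IFIT1 2.70-fold. Each of these 8 lists had an adjusted p = 0.62 with an estimated correlation, and the cholesterol median was −0.49 with median centring.

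Nonsense-mediated decay genes were higher in 20 of 30 cases and lower in none (median 0.39, and 0.22 with median centring; adjusted p = 0.000293), with SNHG1 2.12-fold, SNHG15 2.17-fold and GAS5 1.75-fold higher, and 16 of 20 synthetases were higher and 2 lower (adjusted p = 0.000326). NRF2 targets were lower in 7 of 13 cases and higher in none (adjusted p = 0.00302). Oxidative phosphorylation genes were lower in 16 of 27 and higher in none (adjusted p = 3.05e-05, and 0.0949 after cyclic loess). Ribosomal protein genes were lower in 56 of 78 and higher in none (median −0.26, adjusted p = 9.71e-13). That median was −0.42 with median centring and −0.04 after quantile normalization, where the call was lost (0.205). After cyclic loess it turned to 0.06, and the list passed there (0.0196). These 5 lists had an adjusted p = 0.67 with an estimated correlation. T cell surface and signalling genes were lower in 9 of 22 cases and higher in 4 (adjusted p = 0.00865; adjusted p = 0.75 with an estimated correlation), a call lost after quantile normalization (0.281) and cyclic loess (0.365). The G1/S list, with 10 members higher and 6 lower of 24, did not pass (adjusted p = 0.795); CDC6 was 1.56-fold and E2F2, a replication-linked transcription factor, 1.80-fold higher, while PCNA was 1.66-fold lower. The unfolded protein response list, with 6 higher and 10 lower of 20, did not pass (adjusted p = 0.0565): HERPUD1 was 3.02-fold, XBP1 2.41-fold and EDEM1 2.01-fold higher and HSPA5 2.21-fold lower. Adjusted over the list alone, the higher and lower counts were 1 and 19 for cholesterol, 2 and 19 for hypoxia, 0 and 63 for ribosomal proteins, 4 and 11 for T cell genes and 6 and 11 for the unfolded protein response, and as given for the other lists of this comparison named above.

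GSPT1 was 1.30-fold higher in the libraries titled MI-389 than in those titled sunitinib (adjusted p = 0.000624 by limma), ETF1 1.38-fold, CRBN 1.41-fold, IKZF1 1.22-fold, IKZF3 1.71-fold, ATF4 1.58-fold and MYC 1.82-fold. CDKN1A, 1.51-fold higher, passed narrowly (adjusted p = 0.0488) and did not pass with a pseudocount of 0.1 (0.0602), without short non-coding RNAs (0.0502), with median centring (0.245), after quantile normalization (0.0909) or cyclic loess (0.0684), without replicate 1, 2 or 3 of the group titled MI-389 (0.131, 0.0611 and 0.0596) or without replicate 1 or 3 of that titled sunitinib (0.144 and 0.0822). Of 11 genes of the degrader machinery, 7 were higher and 3 lower, also when adjusted over the list alone (camera, adjusted p = 0.36). Fry gave that list an adjusted p = 0.0143.

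The comparisons with DMSO shared 1151 genes called in one direction, 156 higher and 995 lower in both treated groups. Independent lists of these sizes would share 82.8 and 588. Unchanged groups simulated against the same controls 100 times shared 0, a value that leaves out any real effect and so is no measure of the overlap that such effects would give. Without short non-coding RNAs, the log2 differences correlated across 12048 genes at r = 0.31, where simulation gave 0.53; genes are not independent replicates. Their covariance was 0.0295 against 0.00631 simulated, a difference of 0.0232. The DMSO libraries are too few to split, so part of the excess may come from the shared controls. The shared count moved more than 1.5-fold when single libraries were left out, to 2492 without DMSO replicate 1, 726 without DMSO replicate 2 and 744, 502 and 510 without replicates 1, 2 and 3 of the group titled sunitinib. A further 471 genes were called in opposite directions, 438 of them higher in the libraries titled MI-389.

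**Figure D3:**
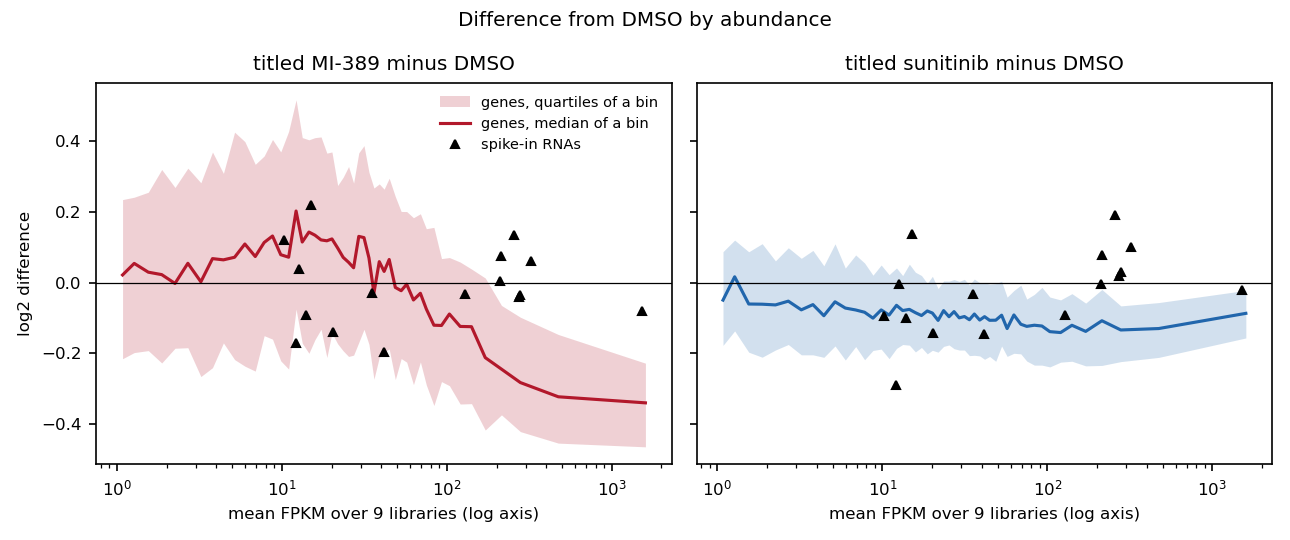
Log2 difference from DMSO against mean FPKM over 9 libraries (log axis) for the libraries titled MI-389 (left) and titled sunitinib (right); lines and bands are the median and quartiles of genes in 50 abundance bins, and triangles are the 16 spike-in RNAs at 10 FPKM or more. In the most abundant bin the gene median was −0.34 on the left and −0.09 on the right, while the 8 spike-in RNAs above 100 FPKM had medians of −0.01 and 0.03.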

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

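The tests of library placement, depth and label fields below were chosen after the results were seen; the splits of libraries were planned. In all, 471 genes were called in opposite directions against DMSO in the treated groups; a selection of this kind makes a difference in the direct test between them nearly certain. CD69, DDIT3, EGR1, JUN, LSS and MYC are those among the largest rises and falls of a comparison or the 11 genes named in every comparison. The log2 difference, libraries titled MI-389 minus libraries titled sunitinib, was 4.22 for CD69, 2.72 for DDIT3, 6.12 for EGR1, 7.52 for JUN, −1.12 for LSS and 0.86 for MYC. The fall of DDIT3 in the libraries titled sunitinib was lost under several settings, such as without DMSO replicate 3 (adjusted p = 0.101).

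For the rise of ATF4 list and immediate early genes in the libraries titled MI-389, 3 explanations were examined. Other technical causes were not tested. A single mislabelled library is argued against, because over both lists the lowest library titled MI-389 lay 1.73 log2 units above the highest of the other 6, with a largest SD of 0.0934 within a group. Between the treated groups a difference in depth is argued against, because they had a modal log2 ratio of −0.05 for the value of a single read. The modal log2 ratio of that value, DMSO to the treated libraries, was 0.454 for those titled MI-389 and 0.4 for those titled sunitinib. Depth thus differed from DMSO in both treated groups, but the libraries titled sunitinib had no comparable rise. Crossed compound names stay open: the source field of 6 of the 6 treated libraries names the other compound, and the namings cannot be told apart because a swap of whole groups leaves every value in place. Such a swap would change the compound to which the rise belongs, not the rise itself. A response of these libraries to the compound they received stays open as a hypothesis.

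Of the 10 splits of 6 libraries into 3 and 3, only the real split called as many genes in each comparison (1 of 10 each); 10 splits are too few for a share under 0.05. The real counts were 6979, 2370 and 6927, and the highest of the other splits were 2, 4 and 2 for the libraries titled MI-389 against DMSO, those titled sunitinib against DMSO and the treated groups. For gene lists the real counts of 14, 12 and 14 were reached by 3, 6 and 6 of the 10 splits, with 16, 17 and 15 lists at most in another split. In each comparison camera with a preset correlation thus called as many lists in some mixed splits as in the real one, and fewer in others. Every mixed split keeps part of the group difference and adds the rest to the spread within its groups. Low gene counts there were therefore fixed in advance, and neither the gene nor the list counts measure what chance would give.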

How the results depend on the processing

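The cyclic loess results below were chosen after the data were seen; the other alternatives were planned. Of 4009 values of named genes under the alternatives other than a fold change of at least 2 and crossed names, 3942 kept their direction and their side of the threshold, 42 lost a call, 13 gained one and 12 turned in sign. Against DMSO, gene counts for the libraries titled MI-389 stayed within 1.5 times except under a fold change of at least 2 or crossed names. Where no cause is given, the cause was not tested. Low values rest on few reads, and the depth of single libraries is unknown.

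Without a filter on low values, where more genes were tested, 1423 genes were called for the libraries titled sunitinib against DMSO (175 higher, 1248 lower), the overlap was 692, and the median log2 difference was −0.0034 there and 0.00040 between the treated groups. With median centring, 1270 genes were higher for the libraries titled sunitinib and 4863 lower between the treated groups; the medians were −0.0807 for the libraries titled MI-389, −0.0088 for those titled sunitinib and −0.0838 between them. The log2 differences were then −0.019 for GSPT1 (titled MI-389), 0.081 for CRBN and 0.038 for IKZF3 (titled sunitinib). After quantile normalization, 3677 genes were called for the libraries titled sunitinib (1696 higher) and 4426 were lower between the treated groups; the overlap was 1863 and the medians −0.0050 and −0.0366. IKZF1 stood at 0.029 (titled MI-389), CRBN at 0.089 and IKZF3 at 0.018 (titled sunitinib). After cyclic loess, 3814 genes were called for the libraries titled sunitinib (1852 higher) and 4040 were lower between the treated groups; the overlap was 1979 and the medians 0.0017 and −0.0082. IKZF1 stood at 0.0496 (titled MI-389), CRBN at 0.10 and IKZF3 at 0.025 (titled sunitinib).

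With only the 6 libraries compared, which leaves fewer samples for the variance, 1225 genes were called for the libraries titled sunitinib (149 higher, 1076 lower) and the overlap was 617. With a fold change of at least 2, 423 genes (294 higher, 129 lower), 18 (4 and 14) and 417 (362 and 55) were called for the libraries titled MI-389, those titled sunitinib and between them, and the overlap was 7. With an estimated correlation 0 gene lists were called in each comparison, and fry called 23 between the treated groups. With compound names from the source field, the counts change places: 2370 genes (291 higher, 2079 lower, median −0.0953) for MI-389 against DMSO, 6979 (3502 higher, 3477 lower, median −0.0021) for sunitinib against DMSO, and 2500 higher and 4427 lower between them (median −0.0812).

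Leaving out each library in turn gave 6007 to 7250 called genes for the libraries titled MI-389 (2921 to 3964 higher, 2855 to 4085 lower, median −0.0363 to 0.0423, 14 to 17 lists). For those titled sunitinib it gave 929 to 4244 (123 to 380 higher, 806 to 3950 lower, median −0.1326 to −0.0480, 10 to 18 lists), the lowest count of called genes without replicate 2 of that group and the highest without DMSO replicate 1. Between the treated groups it gave 5950 to 7594 (3792 to 4725 higher, 1926 to 2874 lower, median 0.0598 to 0.1105, 14 to 17 lists), and the overlap ran from 502 to 2492, again without those libraries. IKZF1 (titled MI-389) ran from −0.107 without DMSO replicate 1 to 0.010 without DMSO replicate 3. CRBN (titled sunitinib) ran from −0.022 without DMSO replicate 2 to 0.022 without DMSO replicate 3, and was 0.0012 without replicate 1 of its group.

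The replicate numbers share only a number: same-numbered libraries of different groups had correlated deviations of −0.08 to 0.18, 1 of 9 pairs over 0.1. With the replicate number as a block, 6816, 1941 and 6740 genes and 15, 12 and 16 lists were called, and the overlap was 940. The list of kinases that sunitinib binds then had a camera adjusted p of 0.0441 for the libraries titled MI-389 against DMSO. Between the treated groups this list had 0.0350 and the lysosome and autophagy list 0.0499. CDKN1A had an adjusted p of 0.0739 by limma between the treated groups.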

Other observations

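The tests of small nucleolar RNA host genes, transcript length and single-exon genes were written before their results were seen; those of abundance, library offsets and spike-in rows were chosen afterwards. Several fixed lists were not described above. In the libraries titled MI-389, 8 of 16 replication-dependent histone genes rose and none fell against DMSO (camera, adjusted p = 0.0751). HIST1H2AC stood at 22.9 ± 1.47 against 4.29 ± 0.696 FPKM (SD, n = 3) and HIST1H1C at 30.1 ± 0.896 against 9.12 ± 0.225. The libraries were made from polyA RNA, so these values may cover only histone transcripts with a polyA tail. Of 27 translation factors 4 rose and 12 fell (adjusted p = 0.25): EIF1, a start codon selection factor, rose 2.29-fold to 1656 ± 20.6 FPKM, EIF2S2, a subunit of the initiator tRNA carrier, rose 2.09-fold, and ABCE1, the ribosome recycling factor that acts after termination, fell 1.99-fold to 104 ± 4.89 FPKM. Among 24 p53 targets 7 rose and 9 fell (adjusted p = 0.78), PLK3, a stress kinase, rising 3.73-fold and PMAIP1, which encodes the BH3 protein NOXA, 3.03-fold. Among 13 BCL2 family genes 5 rose and 4 fell (adjusted p = 0.78), and BCL2L11, which encodes BIM, fell 1.99-fold. TNF, at 7.33 ± 1.02 against 0.681 ± 0.0870 FPKM, rose and CD83 fell 3.02-fold among 12 NF-kB targets, of which 4 rose and 3 fell (adjusted p = 0.35). ISG15 fell 1.90-fold among 18 interferon-stimulated genes, of which 2 rose and 7 fell (adjusted p = 0.26). By fry, which tests a list without the other genes, the adjusted p was 0.000864 for histones and 0.0200 for p53 targets. Fry gave 0.0221 for NF-kB targets and 0.0272 for interferon-stimulated genes, but 0.89 for translation factors and 0.081 for the BCL2 family.

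TAL1, a leukemic transcription factor, fell from 29.9 ± 2.53 to 10.4 ± 0.693 FPKM in the libraries titled MI-389, where its partner LMO2 rose from 9.94 ± 1.19 to 29.9 ± 1.71; of 13 genes of that circuit 5 rose and 6 fell (adjusted p = 0.79). In the libraries titled sunitinib 7 of the 13 fell and none rose (median −0.34, and −0.20 after quantile normalization and −0.21 after cyclic loess; adjusted p = 0.00161; adjusted p = 0.66 with an estimated correlation), TAL1 1.36-fold, LMO2 1.72-fold and MYB 1.38-fold. HES1, a NOTCH1 target, was 1.57-fold higher than DMSO in the libraries titled MI-389 and 1.58-fold lower in those titled sunitinib. Its list did not pass by camera in either (adjusted p = 0.29 and 0.59) but passed by fry in both (0.0233 and 0.0332). RAG1 and RAG2, the recombinase genes, rose 1.51-fold and 1.34-fold in the libraries titled sunitinib. In those titled MI-389 RAG1 stood at 69.0 ± 3.91 against 57.3 ± 3.96 FPKM in DMSO, and RAG2 at 21.1 ± 1.39 against 24.4 ± 1.28. CD1A, a thymocyte marker, fell 1.80-fold in the libraries titled MI-389. It stood at 123 ± 4.90 FPKM in those titled sunitinib against 150 ± 8.62 in DMSO. The T cell list did not pass against DMSO (adjusted p = 0.19 and 0.0686). In the libraries titled sunitinib camera placed it above the other genes after quantile normalization (0.0044) and cyclic loess (0.00777). Of 15 genes of RNA polymerase II and transcription elongation, 12 were higher and 1 lower in the libraries titled MI-389 than in those titled sunitinib (adjusted p = 0.0512), a list that passed with median centring (0.0288), quantile normalization (0.00726) and cyclic loess (0.00696). Against DMSO 9 were higher and 3 lower (adjusted p = 0.0613, and 0.0348, 0.00644 and 0.00885 under these settings). With an estimated correlation the list had an adjusted p = 0.77 between the treated groups and 0.84 against DMSO. Fry gave 0.00428 and 0.0200 there. Of 6 measured kinases that sunitinib binds, 3 were higher and none lower in the libraries titled MI-389 than in DMSO (adjusted p = 0.0632, and 0.0425 with median centring), and none was called in those titled sunitinib (adjusted p = 0.57). Between the treated groups 5 were higher and none lower in the libraries titled MI-389 (adjusted p = 0.0512, and 0.67 with an estimated correlation). There the list passed with median centring (0.0286), quantile normalization (0.0395) and cyclic loess (0.0390). By fry the kinase list had an adjusted p = 0.00799 for the libraries titled MI-389 against DMSO. It had 0.18 for those titled sunitinib against DMSO and 0.00146 between the treated groups. Adjusted over the list alone, the higher and lower counts in the libraries titled MI-389 against DMSO were 7 and 10 for p53 targets, 6 and 6 for the TAL1 circuit, 6 and 11 for T cell genes, 10 and 3 for RNA polymerase II and 5 and 3 for NOTCH1 targets, those in the libraries titled sunitinib were 0 and 9 for the TAL1 circuit, 4 and 4 for T cell genes and 1 and 4 for NOTCH1 targets, and the others named here were as given. Markers of other cell types were too few to test as lists; VIM fell in the libraries titled MI-389 (380 ± 7.88 against 560 ± 60.9 FPKM) and CD79A in those titled sunitinib (6.66 ± 0.578 against 9.07 ± 0.513 FPKM), a call lost with median centring (adjusted p = 0.0551).

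Ribosomal protein transcripts were lower in the libraries titled MI-389 than in DMSO. The margin was small for DMSO replicate 1, with a list median of 11.81 against at most 11.77 in those libraries. A difference that varies with abundance, in the normalization or in the cells, is a candidate explanation: the list's median of −0.28 lay above that of 100% of 10000 abundance-matched lists, whose median was −0.39. Without short non-coding RNAs, the 56 other genes above the most abundant spike-in RNA had a median of −0.41 against −0.29 for the 64 ribosomal protein genes there. The 8 spike-in RNAs above 100 FPKM had a median of −0.01. Spike-in rows may have been levelled by the authors' normalization, which is not given in the sources used here, so these do not decide. A loss of abundant messenger RNA per cell stays open beside a normalization effect.

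More genes were lower than higher in the libraries titled sunitinib. Rescaling to the spike-in rows left 11.96% of calls higher, but these rows were level between the groups, so the rescaling could move little and does not decide. With each library centred on its median 40.5% were higher, but centring itself sets most of that balance, so a technical offset per library and a small fall in messenger RNA per cell cannot be told apart. The exact permutation test of the library medians gave p = 0.2 (two-sided, smallest possible 0.1) and decides nothing either.

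A hypothesis that nonsense-mediated decay was reduced in the libraries titled MI-389 was tested on 8 small nucleolar RNA host genes named SNHG that were outside the fixed list. The prediction written for it was a rise, but 2 rose and 4 fell, and their median log2 difference of −0.33 lay at percentile 4.95 of abundance-matched lists. In the libraries titled sunitinib their median was −0.30, at percentile 0.2, so a low median was not particular to those titled MI-389. The rise of the fixed list did not extend to these genes. They were picked by name, and whether they are targets of the decay was not tested, so the result does not decide whether decay was reduced. Across 11038 genes with a length, 91.6% of those looked up, the log2 difference in the libraries titled MI-389 had a Spearman's rho of 0.18 with the length of the longest transcript, between the bounds of 0.1 and 0.3 set for the test, so whether length plays a part cannot be told apart; genes are not independent replicates. The 211 single-exon protein-coding genes had a median of 0.01, at percentile 34.8 of matched lists, which is evidence against a general rise of intronless genes.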
